A study of Mus musculus with 10 samples.

How the data were processed

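Total RNA was extracted with Trizol from primary mouse keratinocytes grown in low calcium medium, and biotin-labelled cRNA was prepared from 6 µg of it for Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. These are one-colour arrays on which each probe set is a group of short probes against 1 transcript or a few related transcripts. The 10 arrays carry 5 samples labelled Sgpp1+/+ and 5 labelled Sgpp1-/-, and the grouping follows those labels. The labels number the samples 1 to 5 and 8, 9, 10, 21 and 23, and no number occurs in both groups, so the samples were not paired. The labels do not say whether the samples came from separate animals or cultures, nor on which day between 3 and 4 each was harvested, so the p-values measure only the spread between these samples.

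The deposited values are log2 expression values, 1 per probe set and array, made with RMA, per the submitters' processing notes. RMA is robust multi-array averaging, which corrects the background, brings the probe intensities of all arrays to 1 common distribution and combines the probes of a set. The version and the software are not stated in the sources used here. Because RMA compresses differences near the background, a log2 difference of a dim gene understates its change, and because it equalises the arrays, a shift common to most genes could not be seen. The values ran from 1.13 to 14.92, and array medians from 5.03 to 5.17. They were used as deposited, with no further normalisation, no pseudocount and no filter on dim probe sets. The 10 columns of values were all used and 0 columns were left out. The number of arrays, 5 per group, limits the precision.

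Of the 45101 probe sets, 64 are Affymetrix controls and were left out of the gene tests, 34945 were assigned to exactly 1 gene, 932 to several genes and 9160 to none in the table of probe sets and genes used here. For 34741 of the probe sets the gene identifier was found in the table of gene names, which rests on the assembly GRCm38.p6. That table served for names and for which genes neighbour each other, and no position is given because the build behind the probe set table is not stated. For the 9010 genes with several probe sets, the one with the highest mean over the 10 arrays stood for the gene, which gave 18193 genes. Among the 238 genes called that have more than 1 probe set, 17 had another probe set of opposite sign, and 0 of these were past the threshold. Of the 420 other probe sets of these genes, 113 passed in the same direction, adjusted over all probe sets. The probe sets with several genes or none were tested apart.

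Differences were computed as KO minus WT with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by Benjamini-Hochberg over the 18193 genes with a threshold of 0.05. An error given as SE is the moderated standard error of the limma fit, and SD is the spread between the 5 arrays of a group. Single values per array, such as the mean of a list, were compared with an exact permutation test over all 252 assignments of the 10 arrays, for which the smallest two-sided p is 0.00794. Before the data were examined, 30 gene lists were fixed: basal, spinous and cornified keratinocyte genes, barrier lipids, sphingolipid metabolism, calcium handling, the S100 family, the cell cycle, wound keratins and inflammation, interferon response, cholesterol synthesis, endoplasmic reticulum stress, autophagy, immediate early genes, p53 targets, NRF2 targets, Notch, tight junctions, the epithelial to mesenchymal transition, and markers of hair follicle, sebocytes, fibroblasts, melanocytes, Langerhans and myeloid cells, T cells, mast cells, endothelium, muscle, adipocytes, and Merkel cells and neurons. They were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, adjusted over the 30 lists, and again with the correlation estimated per list. limma's fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, was run beside it. With the preset correlation 13 lists were called, 10 higher and 3 lower in KO. With an estimated correlation 3 held, the spinous, cornified and barrier lipid lists, and by fry 4, these 3 and the sphingolipid list. Members of a list were also tested adjusted over the list alone.

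The genes to name were set by a rule written before the data were examined. It takes Sgpp1, the 12 genes higher and the 12 lower with the largest difference among called genes whose groups do not overlap, leaving out placeholder symbols, the 4 members of each called list with the smallest adjusted p, up to 2 called members of each other list, and the most abundant member of each list of another cell type. This gave 93 genes, and genes named outside it are marked as chosen after their values were seen and were not rerun under the alternatives.

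The limma and camera steps were tested on simulated data of 18193 genes with the spread of these arrays for the KO minus WT comparison. In it 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. They were recovered in 7.46%, 73.1% and 95.5% of cases, and 5 of 122 calls (4.10%) were false. Recovery after Benjamini-Hochberg adjustment depends on how many genes change, so these rates need not hold for the real arrays. A shifted list had a camera p of 3.7e-30, and 2 of 100 unshifted lists had a p under 0.05. The genes were simulated independently of each other, so this did not test whether the preset correlation of 0.01 was high enough. On the real arrays the estimated correlation was 0.32 for the cornified, 0.54 for the cell cycle and 0.85 for the melanocyte list.

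Alternatives fixed before the data were examined were a filter on genes below the median signal, a shift to a common median, quantile normalisation and cyclic loess of the deposited values, the mean over all probe sets of a gene, every probe set on its own, leaving out probe sets whose identifiers end in _x_at or _s_at, eBayes with trend and robust settings, array weights, the mean of the Y-linked genes as covariate, KO 8, 9 and 10 alone against all WT, an exact rank-sum test, a threshold of 0.01, limma's treat against a log2 difference of 0.5, both other list tests, and leaving out each array in turn. Chosen after seeing the data were the fibroblast list mean, the poly-A spike-in mean and the array number in the titles as covariates, and leaving out WT 1, WT 2 and KO 8, the arrays with the highest poly-A spike-in signal, or WT 3, WT 4 and KO 23, those with the highest fibroblast list mean. Chance was examined with 100 splits of the 10 arrays into 5 and 5, drawn with a fixed seed, the real split included.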

Results

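Transcript levels were measured in primary keratinocytes, the epithelial cells of the epidermis grown out of mouse skin, from mice labelled Sgpp1+/+ (WT) and Sgpp1-/- (KO). Sgpp1 encodes sphingosine-1-phosphate phosphatase 1, an enzyme that removes the phosphate from sphingosine-1-phosphate, a signalling lipid, and returns sphingosine to ceramide synthesis. The cells had been kept for 3 to 4 days in medium with 0.05 mM calcium and 8% fetal calf serum. Low calcium is the usual way to hold cultured mouse keratinocytes in a basal, proliferating state. There were 5 arrays labelled WT, numbered 1 to 5, and 5 arrays labelled KO, numbered 8, 9, 10, 21 and 23, each hybridised to 1 Affymetrix Mouse Genome 430 2.0 array. Each array gave 45101 probe set values on a log2 scale. Array medians lay between 5.03 and 5.17, and the correlation between pairs of arrays across all probe sets lay between 0.943 and 0.990. Array WT 1 stood farthest from the rest, with a mean correlation of 0.955 with the other arrays against at least 0.967 for each other array.

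The series title names keratinocyte differentiation and the homeostasis of the epidermis as the subject, and the comparison asks which transcripts differ between keratinocytes labelled KO and WT. The targeted gene itself was not lower in the arrays labelled KO. The brightest of its 3 probe sets, which stood for the gene, read 7.67 ± 0.84 in WT and 8.82 ± 0.24 in KO (log2 signal, mean ± SD, n = 5 each), a difference of 1.15 (SE 0.33), or 2.22-fold higher. A probe set of similar brightness read 7.55 ± 0.99 in WT and 8.79 ± 0.19 in KO, and the dimmest read 4.20 ± 0.25 and 4.71 ± 0.20. On all 3 probe sets each array labelled KO lay above each array labelled WT (exact permutation p = 0.00794 for each probe set, two-sided, the smallest that 5 against 5 arrays can give). Over all genes tested, the difference of the brightest had a limma adjusted p of 0.102 and did not pass the threshold. Without array WT 1, the lowest at 6.25, the difference was 0.80 (SE 0.17) with a limma adjusted p of 0.0356, past the threshold. The labels do not say which part of the gene was disrupted, so it is unknown whether these probe sets lie in it, and a probe set outside it checks nothing. Every direction given here rests on the submitters' labels alone, and "KO" and "WT" stand throughout for the arrays labelled so.

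**Figure D1:**
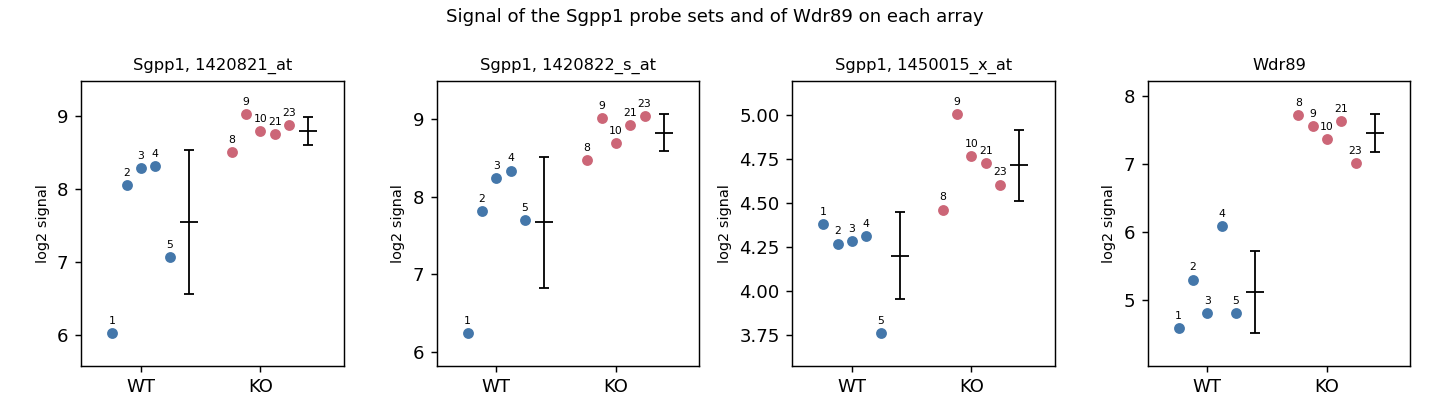
Log2 signal (vertical axis) of the 3 Sgpp1 probe sets and of Wdr89, the next measured gene beside Sgpp1, in arrays labelled WT and KO (horizontal axis); each point is 1 array with its replicate number, and the black bar is the mean ± SD of 5 arrays. All 5 KO points lie above all 5 WT points in each panel, and WT 1 is the lowest point of the brightest Sgpp1 probe set (the second panel from the left) at 6.25.

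Keratinocytes labelled KO carried more transcript of the genes that build the outer layers of the epidermis. Of 18193 genes tested, 419 were higher and 63 lower in KO, and 302 of these 482 differed by at least 2-fold, 279 higher and 23 lower. The largest measured rises among named genes were in late cornified envelope genes, which encode small proteins cross-linked under the membrane of dying keratinocytes. Lce1c went from 3.35 ± 0.95 to 7.54 ± 0.74 (mean log2 signal ± SD, n = 5 each), at least 18.2-fold, and Lce1f, Lce1a2 and Lce1b rose 17.8-fold, 15.4-fold and 12.6-fold. Hrnr, encoding the filaggrin-like protein hornerin, rose from 3.51 ± 0.59 to 7.03 ± 0.20, at least 11.5-fold, with a limma adjusted p of 6.44e-05. Kprp, a keratinocyte proline-rich protein, rose 11.9-fold, and Rptn, encoding the cornified envelope protein repetin, rose 9.93-fold. Other Rptn probe sets differed by 0.18 and 0.79 on the log2 scale and did not pass. The protease inhibitor genes Serpinb11 and Serpinb12 rose 9.61-fold and at least 8.16-fold. Lce1d, Lce1a1 and Sprr2i rose 11.5-fold, 10.8-fold and at least 8.78-fold. In WT, Serpinb12 (3.04), Lce1c and Hrnr read no higher than 3 Y-linked genes do on the 6 arrays without Y-linked signal (2.08 to 3.84), and Sprr2i (3.85) hardly higher. Such a signal may be background, so these 4 ratios are given as lower bounds and their order is uncertain. On single WT arrays other genes also read within that range. Among them were Lce1f on WT 1 (2.19) and WT 4 (2.78) and Lce1a2 on the same arrays (3.67 and 3.80). Their ratios may therefore be too low as well. Members of the Lce1 and Sprr2 families are near-identical in sequence, so a probe set can read several of them and the value of a single member is uncertain.

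The genes lower in KO were fewer and their differences smaller. Akap12, encoding a scaffold protein for protein kinases A and C, went from 8.80 ± 0.30 to 6.82 ± 0.75 (mean log2 signal ± SD, n = 5 each), a 3.96-fold lower level. Kcnn4, a calcium-activated potassium channel gene, fell by 1.94 on the log2 scale with a limma adjusted p of 0.0439. Mmp9, encoding a matrix metalloproteinase, went from 6.79 ± 0.51 to 5.22 ± 0.29, 2.96-fold lower, and Plaur, the urokinase receptor gene, fell by 1.28. Golm2 was 2.82-fold lower, and Tnnt2 fell by 1.27 on the log2 scale, Slc38a1 by 1.23, Kalrn by 1.20, Anp32a by 1.17 and Septin6 by 1.17. Other probe sets of some of these genes moved less. That of Golm2 differed by -0.34 and those of Anp32a by -0.05 and -0.21. Those of Septin6 ran from -0.66 to 0.03, and none of these passed. Kalrn had 1 other that passed, at -1.15, and the rest ran from -0.50 to -0.21. Others of Tnnt2 (-1.24) and Slc38a1 (-1.22) passed, but 1 of Tnnt2 (-0.32) did not. Plod2, encoding a collagen lysyl hydroxylase, fell by 1.14, and Fads2, encoding a fatty acid desaturase, fell by 1.08.

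Both counts come from limma with Benjamini-Hochberg adjustment over the 18193 genes at a threshold of 0.05. In 797 genes (4.38%) the 5 KO values did not overlap the 5 WT values, against 0.794% by chance, and 437 of the 482 called genes were among them. The count of lower genes rested on single arrays: it was 38 without WT 2, 19 without WT 4, 96 without KO 8, 13 without KO 9, 17 without KO 10, 20 without KO 21 and 107 without KO 23, while the count of higher genes was 264 without KO 9, 273 without KO 10 and 285 to 419 without each other array. Of the named genes, 14 lost their call when single arrays were left out, each of them without KO 9, KO 10 or both: Kcnn4, Plaur, Tnnt2, Anp32a, Septin6, Prc1, Mki67, Sqle, Dnajb9, Epgn, Notch3, Gata3, Dpp4 and Piezo2. An exact rank-sum test per gene called 0 genes, but it could call none unless 2888 genes reached its smallest p of 0.00794, and 792 did, so its 0 says nothing about the limma calls. With the array number as a covariate, an alternative chosen after the results were seen, 0 genes were called higher and 0 lower. Of the 419 higher genes 340, and of the 63 lower genes 62, kept at least 50% of their log2 difference there, while the median standard error per gene went from 0.208 to 0.417 and from 0.198 to 0.408.

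Basal and differentiation genes were read as lists fixed before the data were examined. Of 21 measured basal keratinocyte genes, 0 were called, both over all genes and adjusted over the list alone. Krt5 read 12.78 ± 0.06 in WT and 12.73 ± 0.10 in KO, and Krt14 read 12.69 ± 0.14 and 12.72 ± 0.04 (mean log2 signal ± SD, n = 5 each). The median log2 difference of the basal list was 0.13 and its camera adjusted p was 0.157.

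Of 37 spinous and early differentiation genes, 21 rose and 0 fell over all genes tested, and 29 rose and 0 fell adjusted over the list alone. The keratins of the spinous layer, Krt1 and Krt10, rose 3.32-fold and 5.12-fold. Dsc1, encoding the suprabasal desmosomal cadherin desmocollin 1, rose from 8.72 ± 0.58 to 11.14 ± 0.40, and Calm4, encoding a calmodulin-like skin protein, rose from 9.89 ± 0.44 to 12.23 ± 0.14 (mean log2 signal ± SD, n = 5 each). Lypd5 rose 4.97-fold and Gltp, encoding a glycolipid transfer protein, rose 2.29-fold. The list had a median log2 difference of 0.87, a camera adjusted p of 8.2e-33 and an adjusted p of 0.00863 with an estimated correlation.

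Of 64 cornified envelope and late differentiation genes, 50 rose and 0 fell over all genes tested, and 56 rose and 0 fell adjusted over the list alone. Besides the Lce genes and Hrnr, Lor and Flg, encoding the granular layer proteins loricrin and filaggrin, rose 7.72-fold and 5.09-fold. Ivl, encoding involucrin, rose 3.26-fold, and Tgm1, encoding the transglutaminase that cross-links these proteins, rose 2.19-fold. Klk5, encoding a serine protease that cleaves corneodesmosomes during shedding, rose 4.72-fold, and Nccrp1 rose 6.07-fold. The list had a median log2 difference of 1.92, a camera adjusted p of 7.8e-70 and an adjusted p of 0.0160 with an estimated correlation. All 5 KO arrays lay above all 5 WT arrays in the mean of this list and of the spinous list (exact permutation p = 0.00794 for each, two-sided, the smallest possible). Krt1, Krt10, Lor, Flg, Ivl and Tgm1 were chosen as examples after their values were seen.

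**Figure D2:**
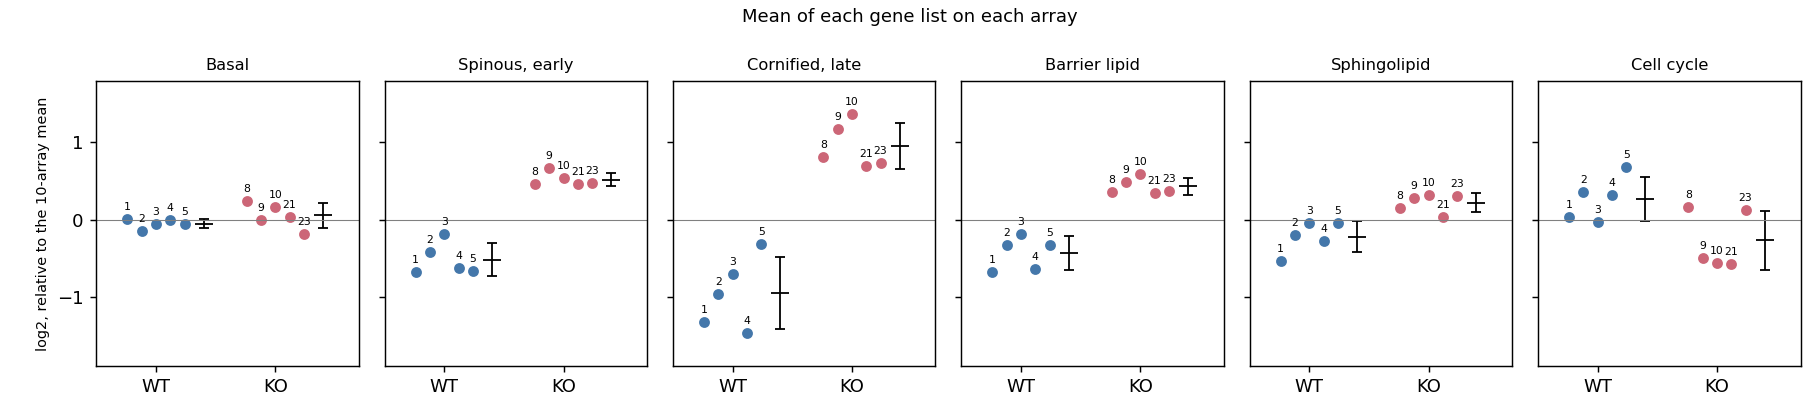
Mean of 6 gene lists on each array (vertical axis, log2 signal relative to each gene's mean over the 10 arrays) in arrays labelled WT and KO (horizontal axis); each point is 1 array with its replicate number, and the black bar is the mean ± SD of 5 arrays. The cornified list runs from -1.46 to -0.31 in WT and from 0.68 to 1.36 in KO, while the basal list stays between -0.18 and 0.24 on all 10 arrays.

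Genes for the lipid barrier moved the same way. Of 41 barrier lipid and ceramide synthesis genes, 17 rose and 1 fell over all genes tested, and 28 rose and 4 fell adjusted over the list alone. Pnpla1, needed to make the acylceramides of the cornified layer, rose 4.03-fold, from 5.78 ± 0.32 to 7.79 ± 0.26, and Sdr9c7, a dehydrogenase that acts on them, rose 5.67-fold, from 7.53 ± 0.56 to 10.03 ± 0.28 (mean log2 signal ± SD, n = 5 each). Dgat2, encoding a triacylglycerol synthase, rose 3.58-fold. The lipoxygenase genes Alox12b and Aloxe3 rose 4.53-fold and 2.65-fold, and Elovl4, encoding the elongase of very long chain fatty acids, rose 3.77-fold. The 1 gene that fell was Fads2. The list had a median log2 difference of 0.84, a camera adjusted p of 1.8e-19 and an adjusted p of 0.0406 with an estimated correlation. Alox12b, Aloxe3 and Elovl4 were chosen after their values were seen.

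Of 45 genes of sphingosine-1-phosphate and sphingolipid metabolism, 7 rose and 0 fell over all genes tested, and 16 rose and 1 fell adjusted over the list alone. The 7 were Acer1, an alkaline ceramidase gene that rose 5.45-fold, Degs2, encoding the enzyme that makes phytoceramides, which rose 7.08-fold, Ugcg, encoding glucosylceramide synthase, which rose 3.13-fold, Sptlc3, a subunit gene of serine palmitoyltransferase, which rose 3.07-fold, Asah2, encoding neutral ceramidase, which rose 2.54-fold, Smpd1, encoding acid sphingomyelinase, which rose 1.89-fold, and Cerk, encoding ceramide kinase, which rose 1.64-fold. Acer1, Degs2, Ugcg, Sptlc3 and Smpd1 are also on the barrier lipid list. Several enzymes that handle sphingosine-1-phosphate directly did not pass over all genes: Sphk1 differed by 0.77 (limma adjusted p = 0.0725), Sphk2 by 0.57 (0.148), the lyase gene Sgpl1 by 0.63 (0.406) and the second phosphatase gene Sgpp2 by -0.02 (0.984). Adjusted over the list alone, Sphk1 (limma adjusted p = 0.0117) and Sphk2 (0.0227) passed, and Sgpl1 (0.114) and Sgpp2 (0.907) did not. Among the receptors the smallest limma adjusted p over all genes was 0.0896, for S1pr4. The list had a median log2 difference of 0.33, a camera adjusted p of 1.7e-07 and an adjusted p of 0.164 with an estimated correlation, which is not past the threshold. Degs2, Smpd1, Cerk and the genes that did not pass were chosen after their values were seen.

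**Figure D3:**
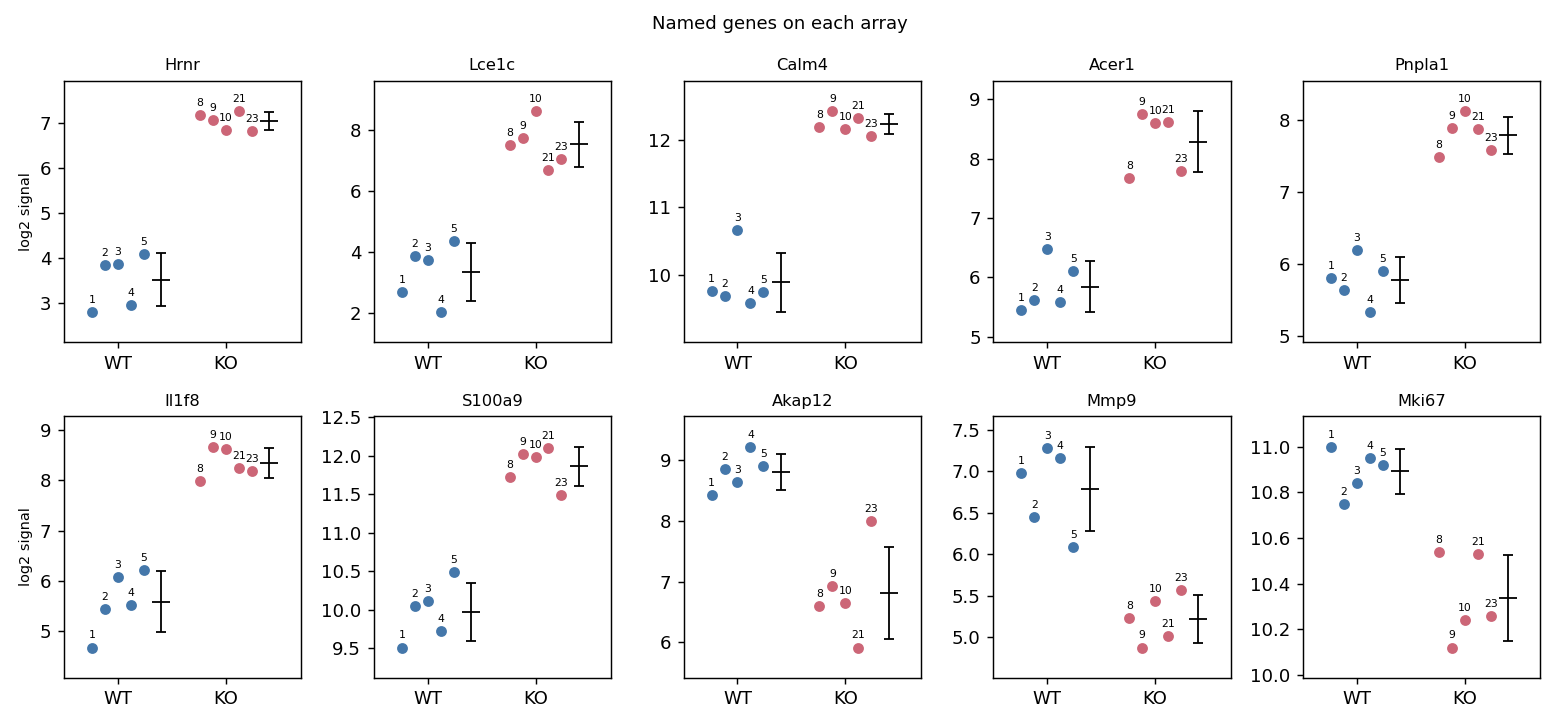
Log2 signal (vertical axis) of 10 named genes in arrays labelled WT and KO (horizontal axis); each point is 1 array with its replicate number, and the black bar is the mean ± SD of 5 arrays. The WT and KO points do not overlap in any of the 10 panels, with Hrnr, Lce1c, Calm4, Acer1, Pnpla1, Il1f8 and S100a9 higher and Akap12, Mmp9 and Mki67 lower in KO.

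Of 41 genes for wound keratins and inflammatory mediators, 9 rose and 1 fell over all genes tested, and 12 rose and 4 fell adjusted over the list alone. Il1f8 and Il1f9, current symbols Il36b and Il36g, encode epithelial cytokines of the interleukin-1 family and rose 6.71-fold and 5.35-fold. Il18 rose 3.96-fold, and Il1rn, encoding the interleukin-1 receptor antagonist, rose 2.18-fold from 8.10 ± 0.27 to 9.23 ± 0.09 (mean log2 signal ± SD, n = 5 each). The 1 gene that fell was Mmp9. The list had a median log2 difference of 0.10, a camera adjusted p of 0.0299 and an adjusted p of 0.448 with an estimated correlation. Of 12 S100 genes, 2 rose: S100a8 and S100a9, which encode the subunits of calprotectin, by 3.82-fold and 3.70-fold. The S100 list as a whole was not called (camera adjusted p = 0.185).

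Of 58 cell cycle and proliferation genes, 0 rose and 2 fell over all genes tested, and 0 rose and 20 fell adjusted over the list alone. Mki67, the proliferation marker Ki-67, went from 10.90 ± 0.10 to 10.34 ± 0.19 and Prc1, encoding a regulator of cytokinesis, from 8.56 ± 0.31 to 7.62 ± 0.39 (mean log2 signal ± SD, n = 5 each). Kif20a and Ccna2 differed by -0.94 and -1.08 with limma adjusted p of 0.0538 and 0.0571 and did not pass. The list had a median log2 difference of -0.55, a camera adjusted p of 9.8e-18 and an adjusted p of 0.317 with an estimated correlation. Its mean on KO 8 and KO 23, at 0.17 and 0.12, lay within the WT range of -0.04 to 0.67 (log2 signal relative to the 10-array mean), while KO 9, KO 10 and KO 21 lay between -0.57 and -0.49.

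Smaller differences were called by camera in 4 further lists, none of them with an estimated correlation. Of 21 cholesterol synthesis genes 1 rose over all genes and 4 adjusted over the list alone. The 1 was Sqle, encoding squalene epoxidase, by 0.64 on the log2 scale, while Msmo1, Ebp and Hsd17b7 differed by 0.65, 0.55 and 0.66 and did not pass over all genes. The camera adjusted p of this list was 8.9e-05 and its adjusted p 0.351 with an estimated correlation. Of 30 genes of endoplasmic reticulum stress 1 rose over all genes and 2 adjusted over the list alone. The 1 was the chaperone gene Dnajb9, by 1.37, while Syvn1, Xbp1 and Herpud1 differed by 0.68, 0.63 and 0.52 and did not pass over all genes. The camera adjusted p of this list was 9.1e-05 and its adjusted p 0.351 with an estimated correlation. Of 24 autophagy genes 0 were called over all genes and 6 were higher adjusted over the list alone, with differences of 0.62 for Gabarapl2, 0.56 for Atg13, 0.50 for Atg9a and 1.06 for Bnip3. Its camera adjusted p was 4.3e-06 and its adjusted p 0.281 with an estimated correlation. Of 30 immediate early and EGFR ligand genes 3 rose over all genes and 4 adjusted over the list alone. The 3 were Egr3 by 2.09, the EGFR ligand gene Epgn by 1.10 and Zfp36 by 0.78, while Jun differed by 0.58 and did not pass over all genes. Another Egr3 probe set differed by 0.07 and did not pass. Of the same list, Fosb read 9.22 on WT 1, 7.60 on WT 2 and 7.36 on KO 8 against at most 4.31 on any other array, and Fos at least 8.45 against at most 7.44 (log2 signal). These 3 arrays also had the highest poly-A spike-in signal, and without them Epgn and Zfp36 lost their call. Both also lost it without WT 3, WT 4 and KO 23, and Epgn in 7 fits that left out single arrays. The camera adjusted p of this list was 0.00222 and its adjusted p 0.281 with an estimated correlation. The medians of the 4 lists were 0.26, 0.23, 0.33 and 0.24 in the order given.

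The remaining lists of keratinocyte programmes were not called by camera. Of 44 calcium channel, pump and calcineurin genes 0 passed, with a camera adjusted p of 0.797, a median of 0.04 and a mean of -0.03. Among 32 NRF2 and oxidative stress genes Me1 rose 1.98-fold and Gsr, encoding glutathione reductase, fell by 0.85 on the log2 scale, with a camera adjusted p of 0.967, a direction of lower in KO and a mean of 0.05. Adjusted over the list alone, 2 NRF2 and oxidative stress genes rose and 3 fell. Of 21 Notch genes 1 rose over all genes, Notch3, 2.40-fold, and 3 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0791). The mean of the Notch list was nevertheless higher on all 5 KO arrays than on any WT array, at -0.09 ± 0.11 in WT and 0.09 ± 0.06 in KO (log2 signal relative to the 10-array mean, mean ± SD, n = 5 each). Its exact permutation p was 0.00794, adjusted 0.0476 over the 30 lists, the same as for the spinous, cornified, barrier lipid and sphingolipid lists. This is the smallest p possible and does not depend on the width of the gap. For the Notch list the gap was narrow, with 0.0160 on KO 21 against 0.0075 on WT 3. Notch3 is also on the spinous list. The p53 target list (21 genes, camera adjusted p = 0.121), the interferon list (32 genes, 0.0543), the tight junction list (20 genes, 0.549) and the list of factors of the epithelial to mesenchymal transition (19 genes, 0.0543) held 0 called genes each over all genes. Adjusted over the list alone, 1 tight junction gene was higher and 1 lower, and the rest of these lists held 0. On leaving out single arrays, camera called the epithelial to mesenchymal list lower in 5 of 10 fits, the interferon list lower in 4 and the Notch list higher in 3.

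Markers of other cell types that a skin culture could hold were read as lists too. The difference of the list mean was -0.37 for fibroblasts (SD 1.43 in WT and 0.58 in KO) and -0.33 for Langerhans and myeloid cells (0.52 and 0.60), less than the SD of either group. It was 0.57 for melanocytes (0.97 and 0.49) and -0.47 for muscle (0.80 and 0.25), less than the WT SD but more than the KO SD. Of 29 fibroblast genes 1 rose, Dpp4, 2.25-fold, and 0 fell, though other Dpp4 probe sets differed by 0.01 to 0.52 and did not pass. The mean of this list was 8.16 on WT 3, 7.88 on WT 4 and 6.94 on KO 23 against at most 6.36 on the other arrays, and 6.46 ± 1.43 in WT and 6.09 ± 0.58 in KO (mean log2 signal ± SD, n = 5 each, exact permutation p = 0.603, two-sided). Its most abundant gene, Sparc, differed by -0.64 with a limma adjusted p of 0.670. The list was not called by camera, but was called lower in 5 of 10 fits that left out single arrays. The lists called by camera were melanocytes, higher in KO (14 genes, median 0.59, camera adjusted p = 0.00829, adjusted p = 0.597 with an estimated correlation), Langerhans and myeloid cells, lower (25 genes, median -0.24, 0.0452 and 0.597), and muscle, lower (19 genes, median -0.48, 0.00222 and 0.467). All 3 held 0 called genes. Of the melanocyte genes Trpm1 differed by 1.20, Pmel by 0.78, Ednrb by 0.74, Mlana by 0.67 and Tyrp1, the most abundant, by 0.91. Of the myeloid genes Epcam, which some keratinocytes also express, differed by -0.50, C1qb by -1.98, C1qa by -0.94 and Cd74 by -0.28. Of the muscle genes Tnni2 differed by -0.61, Cnn1 by -0.52, Tnnc2 by -0.65, Tagln by -1.23 and the most abundant, Tpm2, by -0.06.

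**Figure D4:**
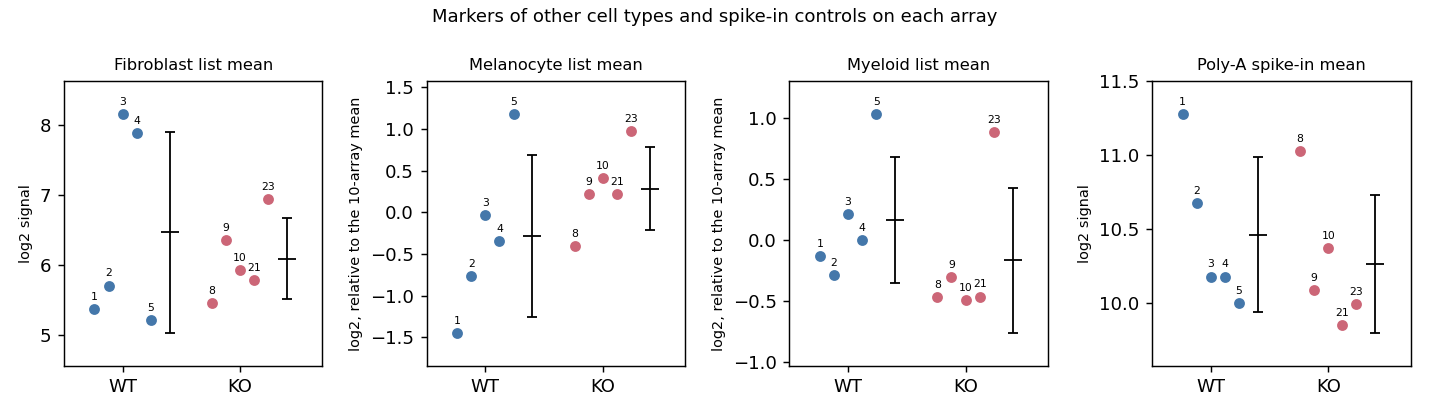
Means of the fibroblast, melanocyte and myeloid lists and of the poly-A spike-in probe sets on each array (vertical axis, log2 signal, for the melanocyte and myeloid lists relative to each gene's mean over the 10 arrays) in arrays labelled WT and KO (horizontal axis); each point is 1 array with its replicate number, and the black bar is the mean ± SD of 5 arrays. The fibroblast mean is highest on WT 3 at 8.16 and WT 4 at 7.88, and the spike-in mean on WT 1 at 11.28 and KO 8 at 11.03.

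The other 7 marker lists were not called. Hair follicle genes (28, camera adjusted p = 0.712) held 1 gene that rose, Gata3, 1.59-fold, and Sox9, the most abundant, differed by -0.04. Sebocyte genes (10, 0.207) held 1 gene that rose, Cidea, 3.58-fold, and Plin2 differed by 0.80 with a limma adjusted p of 0.0535. Merkel cell and neuron genes (10, 0.0578) held 1 gene that fell, the mechanosensitive channel gene Piezo2, by 1.73 on the log2 scale, and Ncam1 differed by -1.24 and did not pass. Another Piezo2 probe set differed by -0.27 and did not pass. Camera called the Merkel cell and neuron list lower in 4 of 10 fits that left out single arrays. T cell genes (11, 0.560), mast cell genes (10, 0.797), endothelial genes (16, 0.0981) and adipocyte genes (8, 0.560) held 0 called genes each over all genes, and their most abundant members, Cd247, Tpsb2, Flt1 and Lpl, differed by 0.02, 0.12, -0.89 and -0.01. Adjusted over the list alone, 1 endothelial gene and 2 Merkel cell and neuron genes were lower, and 1 hair follicle gene and 2 sebocyte genes were higher. In 4 of the 7 lists the group difference of the list mean was larger than the SD within each group. The Merkel cell and neuron mean read 0.27 ± 0.32 in WT and -0.27 ± 0.32 in KO (log2 signal relative to the 10-array mean, mean ± SD, n = 5 each, exact permutation p = 0.0238, adjusted 0.0794). The differences were 0.18 for adipocytes (exact permutation p = 0.0556), -0.16 for endothelium (0.0873) and 0.24 for sebocytes (0.0873).

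Of 3 measures of RNA handling, none had an exact p under 0.05. The poly-A spike-in probe sets read 10.47 ± 0.52 in WT and 10.27 ± 0.47 in KO (mean log2 signal ± SD, n = 5 each, exact permutation p = 0.548, two-sided), and the 3' minus 5' difference of the Gapdh control probe sets was 1.89 ± 0.13 and 1.90 ± 0.22 (exact permutation p = 0.921). The same difference for Actb was 0.24 ± 0.05 in WT and 0.20 ± 0.04 in KO (exact permutation p = 0.159). The array titles place the WT arrays first, as arrays 1 to 5, and the KO arrays as 6 to 10, so a step between arrays 5 and 6 cannot be told apart from the group. A gradual drift can be fitted only with a large error, as number and group run together: with the array number as covariate the median standard error of the 71 called cornified and spinous genes went from 0.272 to 0.536. Within the groups the slope of the cornified list mean per array was 0.15 (SE 0.15) in WT and 0.18 (SE 0.04) in KO, in log2 units.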

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

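The tests of the cornified and spinous genes and of the Sgpp1 signal, the array number as covariate, and the count of lower genes kept with the fibroblast mean as covariate, were chosen only after those results were seen.

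Of 254 groups of 5 arrays looked at, 15 had a highest or lowest array far from the other four by Dixon's ratio, and chance alone gives about 1 in 20, or 12.7. Among single genes (log2 signal), Plod2 was lowest on WT 2 at 7.34 against 7.88 for the nearest WT array, Calm4 highest on WT 3 at 10.67, Nccrp1 lowest on WT 4 at 6.81, Ccna2 lowest on WT 3 at 9.34 and Notch3 lowest on KO 8 at 6.79. C1qa, a macrophage complement gene, was highest on KO 23 at 6.56 against 4.08 for the next KO array, and the mean of the Langerhans and myeloid list was highest on the same array at 0.89 (log2, relative to the 10-array mean) against -0.30. Cd74 was highest on WT 1 at 5.26 and Cd247 lowest on WT 1 at 7.25. The dimmest Sgpp1 probe set was lowest on WT 5 at 3.76. Among list means, the calcium list was lowest on WT 5 at -0.14, the NRF2 list highest on WT 2 at 0.19, the T cell list lowest on WT 5 at -0.37 and the mast cell list highest on WT 1 at 0.10. Array WT 1 had the lowest mean correlation with the other arrays, 0.955. Of the 10092 probe sets with no gene or several genes, which the gene tests do not use, 23 were higher and 2 lower in KO (limma, adjusted over these probe sets).

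The first pattern is the set of genes called between KO and WT. Chance is argued against for the counts of genes, since 1 of 100 splits, the real one, gave as many in all (482 against at most 1 in another split), higher (419 against 1), lower (63 against 0) or changed at least 2-fold (302 against 1). Likewise 1 of 100 gave the 3 lists called with an estimated correlation (against 0), and 1 of 100 is the smallest share possible here. For the 13 lists called with the preset correlation chance stays open, since 16 splits gave as many and the highest other gave 17. Every other split mixes arrays 1 to 5 with 6 to 10, so the splits cannot tell the genotype from the array order. The Y-linked mean argues against a different mix of sexes: it was 7.25 and 7.48 on WT 3 and WT 5, and 7.92 and 7.98 on KO 10 and KO 23. On the other arrays of both groups it was at most 3.45. With this mean as covariate 451 genes passed, but being alike in both groups it could remove few calls. With the fibroblast mean as covariate, 62 of the 63 lower genes were still called lower. That count does not decide on a different share of fibroblasts as their source. These genes were called on the same arrays, and the fibroblast mean differed little between the groups (exact permutation p = 0.603). The test of Col1a1, Col1a2, Col3a1 and Sparc, of which 0 of 4 passed, decides nothing either. Their SE of 0.47 to 1.02 is too large, and all 4 lay lower in KO. Alleles that travel with the targeted locus cannot account for most of the set by their own expression, since 465 of the 482 genes lie on other chromosomes, but they stay open near Sgpp1: 3 of 176 measured genes within 10 Mb were called (exact 95% interval 0.353% to 4.90%) against 479 of 18016 others (2.66%), Fisher's exact one-sided p = 0.849. With the array number as covariate the mean difference was 1.13 (SE 0.22) against 1.40 (SE 0.12) in the 419 higher genes. It was 1.02 (SE 0.25) against 1.00 (SE 0.12) in the 63 lower ones. Both stayed above 0, in the direction called, by more than 2 SE. These genes were called for their group difference on these same arrays, and only a linear drift was fitted. The means therefore cannot decide whether a gradual drift was the whole source or lay behind a part of the set. With this covariate 0 genes were still called, and the median standard error per gene grew from 0.208 to 0.417 and from 0.198 to 0.408. A step between arrays 5 and 6 and any difference in culture also stay open.

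The second pattern is the rise of the cornified and spinous genes, 71 called genes with a mean log2 difference of 2.02 (SE 0.22). With the cell cycle list's mean as covariate the mean difference was 1.94 (SE 0.31), but only 24 of the 71 genes were still called: at the p limit of the fit without covariate 63 stayed past it with only the differences exchanged for those with covariate, 52 with only the errors, 69 with only the degrees of freedom and 46 with all of these, and a new adjustment left 24, so no single part accounts for the loss. The test was first set as the count of genes still called, which at 24 would have counted for slower cycling. It was replaced by the mean difference after that count had been seen. The mean hardly moved, but these genes were called for their group difference on these same arrays. It therefore decides neither whether slower cycling was the whole source nor whether each gene holds. The 2 KO arrays with a cell cycle mean in the WT range, KO 8 and KO 23, both lay above the highest WT array in the cornified mean. Every KO array did, so this outcome was known beforehand. It shows only that on these 2 arrays the higher cornified mean came without a cell cycle mean below the WT range. With the melanocyte list's mean as covariate the mean difference was 1.88 (SE 0.21), and 65 of the 71 genes were still called. With the array number as covariate the mean difference was 1.33 (SE 0.37), above 0 by more than 2 SE. There 0 genes were still called, at a median standard error of 0.536 against 0.272. The 71 genes were called for their group difference on these same arrays, and only a linear drift was fitted. That mean therefore cannot decide whether a gradual drift was the whole source of the rise or lay behind a part of it. A hypothesis left open is that keratinocytes labelled KO may start differentiation at low calcium; a difference in culture age, density or serum calcium between the groups was not tested and could give the same rise.

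The third pattern is the Sgpp1 signal, higher in all 5 arrays labelled KO. It does not come from WT 1 alone, since the difference was 0.80 (SE 0.17) without that array. A disrupted gene whose probe sets still read a transcript, or whose transcript is still made, and an exchange of the labels between the groups both stay open: all 3 probe sets were not lower in KO, and 5 of 5 KO arrays lay above the highest WT array. In WT the signal was far above the middle of the array, at percentile 83.4 of the probe sets, against 91.9 in KO. That rank compares probe sets of different genes, so it does not decide on an exchange of labels. The location of the probe sets relative to the disrupted part could decide between these explanations and is not in the labels.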

How the results depend on the processing

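The fibroblast, spike-in and array number covariates and the settings without WT 1, WT 2 and KO 8 or without WT 3, WT 4 and KO 23 were chosen after seeing the data; all others were fixed before. The cause of the differences between settings was not tested, except where fewer arrays or a stricter threshold bring them. With the array number as covariate all 57 named genes called lost their call, and the median standard error per gene went from 0.239 to 0.488. All 57 kept their direction, and 46 kept at least 50% of their log2 difference (the gene Hrnr 3.23 of 3.52, the gene Calm4 2.37 of 2.34) and 11 less (the gene Kprp 1.11 of 3.58, the gene Sprr2i 0.88 of 3.13). In the other 24 settings 36 kept it in all and 21 lost it in at least 1, 124 of 1363 tests in all; 17 calls were lost without WT 1, WT 2 and KO 8. None reversed in any of the 25 settings (0 of 1420 tests). The spinous, cornified and barrier lipid lists kept their call in all 27 settings. The sphingolipid, cell cycle, cholesterol and endoplasmic reticulum stress lists lost it in 2 each and the autophagy and immediate early lists in 3, but the wound list in 12, the myeloid list in 12, the melanocyte list in 9 and the muscle list in 6, and the wound, endoplasmic reticulum stress and melanocyte lists reversed in 1 more. Lists not called gained a call in 59 of 454 tests: the interferon list in 14, the epithelial to mesenchymal list in 13, the fibroblast list in 11, the Merkel cell and neuron list in 9, the Notch list in 8, the basal list in 3 and the tight junction list in 1. The number of arrays and, for dim genes, the signal over background limit all of these.

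The counts of genes higher in KO and genes lower in KO, and the Sgpp1 KO minus WT difference, moved as follows. A shift to a common median gave 40 lower genes and KO 8, 9 and 10 alone gave 29. Array weights gave 877 higher, 561 lower and 465 at least 2-fold, with 61.0% higher against 86.9%, and an Sgpp1 difference of 0.77 (adjusted p 0.0383); the fibroblast covariate gave 110 lower and an Sgpp1 difference of 1.30 (adjusted p 0.0147). Without WT 3, WT 4 and KO 23, 266 genes were higher, and 274 of the 482 genes were kept. With the array number as covariate there were 0 higher, 0 lower and 0 at least 2-fold, and the Sgpp1 difference was 0.42 (adjusted p 0.901). The exact rank-sum test also gave 0 of each, which its smallest p sets, a threshold of 0.01 gave 218 higher and 10 lower, and treat gave 122. The lists called were 3 with an estimated correlation and 4 by fry. Leaving out each array in turn, Sgpp1 ranged from 0.80 (without WT 1, the one setting of these past the threshold) to 1.32, higher genes from 264 to 419 and lower genes from 13 to 107.

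The directions that reversed were of genes not called and of lists, 3 of them called. The gene Sox9 was 0.0484 with KO 8, 9 and 10 alone and from -0.148 to 0.0742 leaving out single arrays. The gene Cd247 was -0.0324 as the mean of its probe sets, -0.0872 with array weights, -0.0848 with KO 8, 9 and 10 alone, -0.0822 with the spike-in covariate, -0.0737 without WT 1, WT 2 and KO 8, and from -0.129 to 0.0871 leaving out single arrays. With the array number as covariate the gene Trpm1 was -0.146, the gene Ednrb -0.597, the gene Pmel -0.897, the gene Mlana -0.820, the gene Tyrp1 -1.40, the gene Cd74 0.236 and the gene Cd247 -0.298. The gene Tpm2 was 0.0668 without WT 3, WT 4 and KO 23. The gene Lpl was 0.00485 with a common median, 0.0691 with KO 8, 9 and 10 alone, 0.0324 with the fibroblast covariate, 0.0526 without WT 3, WT 4 and KO 23, and from -0.203 to 0.106 leaving out single arrays.

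Of the list means, that of the list calcium channels, pumps and calcineurin signalling was 0.0518 in genes above the median signal and 0.0213 without WT 1, WT 2 and KO 8. The list tight junction and claudins was 0.0312 with array weights and 0.0402 without WT 1, WT 2 and KO 8, and the list epithelial to mesenchymal transition factors was 0.0941 without WT 3, WT 4 and KO 23. The list other cell type: hair follicle and hair shaft was 0.0367 in genes above the median signal, 0.0485 with array weights, 0.0163 with the spike-in covariate, 0.0871 without WT 1, WT 2 and KO 8, and from -0.101 to 0.0429 leaving out single arrays. The fibroblast list was 0.452 without WT 3, WT 4 and KO 23, past the camera threshold there, and from -0.686 to 0.0508 leaving out single arrays. Leaving out single arrays, the list interferon response ranged from -0.496 to 0.0518 and the T cell list from -0.0503 to 0.0823. With the array number as covariate, the list basal keratinocyte was -0.00737, the list calcium channels, pumps and calcineurin signalling 0.0316, the list wound keratins and inflammatory mediators -0.180, the list endoplasmic reticulum stress and unfolded protein response -0.0377, the list p53 targets -0.0657, the list other cell type: hair follicle and hair shaft 0.266, the list other cell type: endothelium 0.00883 and the list other cell type: melanocyte -0.761, past the camera threshold there as lower in KO.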

Other observations

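The groupings here were all chosen after the values were seen. Grouping all genes by the stem of their symbol gave 539 families with at least 5 measured members and 1078 one-sided Fisher's exact tests, of which 9 passed at an adjusted p of 0.05, all for more calls of genes higher in KO than among other genes. Beside Lce (12 of 15 members called, adjusted p = 8.78e-15), Sprr (7 of 9, 6.1e-08) and Tgm (3 of 6, 0.0276), they were Sdr (4 of 5, 4.89e-04), Serpinb (6 of 18, 5.7e-04), Klk, the kallikrein proteases (6 of 20, 7.88e-04), Tmprss, membrane-bound serine proteases (5 of 12, 7.88e-04), Gramd (3 of 5, 0.0180) and Dnase (3 of 6, 0.0276). The families share sequence, so their members are not independent tests. Single genes for transcription factors that rose, also chosen after their values were seen, were Klf4 by 0.99, Grhl1 by 1.01, Prdm1 by 1.35, Pou2f3 by 1.66, Cebpa by 1.08 and Mxd1 by 1.47 (log2, limma adjusted p from 0.00293 for Mxd1 to 0.0302 for Prdm1). Nothing is claimed for such genes as a group: on the spinous list Zfp750 differed by 0.52 (limma adjusted p = 0.0536), Grhl3 by 0.63 (0.170), Ovol1 by 0.66 (0.206) and Barx2 by -0.01 (0.994), and none of these passed over all genes.

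Single genes that fell, picked from the 63 lower ones after their values were seen, were Adam12 by 2.33 on the log2 scale, Vcan by 1.91, Tnc by 1.01, Has2 by 0.94 and Thbs1 by 0.86. The WT and KO values of each overlapped, and no list of matrix genes was tested. The fibroblast list mean was highest on WT 3 at 8.16 and WT 4 at 7.88. The interferon list mean was highest on WT 5 at 1.27 and KO 23 at 0.92 (log2, relative to the 10-array mean), and the same 2 arrays had the highest means of the melanocyte list, 1.18 and 0.98, and of the myeloid list, 1.04 and 0.89.

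Wdr89, the next measured gene beside Sgpp1 in the assembly GRCm38.p6, rose from 5.12 ± 0.61 in WT to 7.46 ± 0.28 in KO (mean log2 signal ± SD, n = 5 each), a difference of 2.34 (SE 0.26, limma adjusted p = 4.56e-04). Of the 5 nearest measured genes on each side of Sgpp1 it was the only one called, and Syne2, the nearest on the other side, differed by 0.28 with a limma adjusted p of 0.670. A hypothesis is that the targeted allele affects its neighbour, which was not tested. Over the 10 Mb on either side 3 genes were called, a count that concerns linked alleles across the region and does not decide it.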
